A study of Mus musculus with 2 samples.

How the data were processed

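DNase-seq libraries of cerebellum tissue from 2 female B6CASTF1/J mice aged 2 months were analysed, 1 library per animal; the labels number them as biological replicates 1 and 2 and their descriptions name different animals, but both carry the same donor identifier. They were taken as 2 animals, and if that is wrong, the SD over replicates is technical. Both form 1 group, and no contrast between groups exists. The depth enters through the heights, as described below, and read totals were not used here. The animals are hybrids of 2 strains while the files are on mm10, the assembly of the C57BL/6J parent, so reads with CAST/EiJ variants can align less well or elsewhere; how alignment dealt with this is not given in the sources used here.

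The authors deposited 4 kinds of files per library. Per the labels, the assembly is mm10; the aligner, the caller and their settings are not given in the sources used here. In the deposited peak lists, the height of a site is a signal value whose scaling is not described in the sources used here. Within a library all heights were whole multiples of 1 step (tolerance 0.05 step), which was read as scaling by library. The authors' scale means the heights as deposited. Heights were used to rank sites within a library and to describe the ratio between libraries, which therefore rests on the authors' scaling; it was also taken in unscaled steps, each height over the step of its library, an alternative added after the data were seen. The deposited FDR track gives a q-value type of p-value per stretch of bases and lists values under 0.05 only. Sites were called per library and not on pooled libraries, since each library has its own lists. Every site of the longer list touched the FDR track of its library, and every site of the shorter list touched bases with an FDR of 0.001 or less; the longer list was the main one, and 84834 of the 85949 shorter-list sites of replicate 1 and 99784 of the 101879 of replicate 2 overlapped it. The deposited footprint files hold positions and 1 constant value whose meaning is not stated, so positions alone were used.

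Sites were compared with bedtools 2.31.1, with an overlap of at least 1 bp; chance overlap came from 10 seeded placements of the same sites on the same chromosome. Paired sites are those that overlap each other best. Heights were compared on the log2(height + 1) scale for correlations and as log2 ratios otherwise. The annotation was GENCODE M21 on GRCm38.p6, the same build as mm10, and the genome sequence that of GRCm38.p6. A promoter site lies within 1000 bp of any annotated TSS; other sites were assigned to exons, introns or intergenic sequence by their middle. Distal sites are over 1000 bp from any TSS and were counted over the gene body and 10 kb on each side.

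24 gene lists were fixed before the data were examined: markers of granule neurons, Purkinje cells, cerebellar interneurons, unipolar brush cells, Bergmann glia and astrocytes, the oligodendrocyte lineage, microglia, vascular and mural cells, and choroid plexus and ependyma; pan-neuronal, forebrain, and hindbrain and cerebellar patterning genes; hepatocyte, erythroid, striated muscle and lymphocyte genes; housekeeping, immediate early and imprinted genes; genes that escape X inactivation (with Xist), Y-linked genes, Hox clusters, olfactory receptors and clustered protocadherins. All members were found in the annotation. Each list was placed as a percentile among 10000 random lists of protein-coding genes of the same size matched on gene length decile, a description of these libraries and not a p-value. Lists at or above the 95th or at or under the 5th percentile were taken as standing apart. The genes named in the text followed a rule fixed before the data were examined: per list the 3 members with the highest promoter site by mean rank and up to 3 with none, all members of lists of 5 or fewer, the 10 highest shared sites with the nearest TSS, the 10 genes with the most shared distal sites, the 3 highest sites of each replicate alone, and the 5 motifs with the highest and the 5 with the lowest ratio. Some of these are left out for brevity, and the values of some list members are not reported here; genes and motifs named beyond the rule are further values of the same tables.

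For 27 consensus sequences, matches on either strand were counted in footprints extended by 5 bp on each side and in windows of the same width in the same site outside footprints; footprints with no room for such a window were left out (76.7% and 89.5% of the footprints in sites kept). The log2 ratio of the shares had 0.5 added to each count, and its 95% interval (1.96 standard errors) covers counting error only. HNF1 and P53 had no match and are among the 5 of 27 that were neither more nor less frequent. The height ratio between replicates was compared for all 27 consensus sequences, over all shared sites and over distal ones, and CTCF was followed up because it stood out there. Differences between sites with and without a CTCF consensus were also taken within deciles of mean height or GC content. For sites on Y, the share of 24-base words found on X or an autosome was counted, with 500 X sites per replicate as the comparison.

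Values are given as mean ± SD over the 2 replicates (n = 2) and no p-value was computed, because there are not 2 groups to compare and sites or genes are not replicates. Shares of sites have Wilson 95% intervals, which cover counting error only. The functions were tested on simulated data: 60% planted overlap among 20000 sites was recovered as 60%, 5% of 20000 footprints with a planted CTCF match as 5.04% (1 of 26 other motifs also left out 0), a planted log2 difference of 0.5 as 0.499, and 99 of 100 lists planted at 95% passed the 95th percentile, as did 10 of 100 unchanged lists. The last count is above the nominal 5, so the 95th percentile is a lenient limit here. Alternatives fixed before the data were examined were the shorter list, other overlaps, promoter windows, gene extensions, pseudocounts, backgrounds and random lists, and leaving out each replicate. In the alternatives, the shorter list stood for both a stricter threshold and the other deposited list. Its threshold was inferred from the FDR track, and some of its sites overlapped none of the longer list. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9, and samtools 1.23.1.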

Results

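Open chromatin was profiled by DNase-seq, in which nuclei are cut with DNase I and the cut ends are sequenced, in the cerebellum of 2 female B6CASTF1/J mice aged 2 months. These animals are first-generation hybrids of C57BL/6J and CAST/EiJ. Both libraries belong to 1 group, and the labels name no contrast, so every comparison is between the 2 biological replicates or between classes of genes and sites within them. Each library has a list of accessible sites with a height per site, a second and shorter list, a track of bases with a false discovery rate (FDR) under 0.05 and a list of footprints, which are short stretches protected from cutting inside accessible chromatin. The heights of replicate 1 were whole multiples of 0.00617 and those of replicate 2 of 0.00377 (100% of sites in each, within 0.05 of a step). If 1 step stands for 1 count scaled by library size, replicate 2 was 1.64 times as deep. Coordinates are those of mm10.

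Genes that mark the main neuron of the cerebellum were open at their promoters without exception. All 16 granule neuron genes, a list fixed before the data were examined, had an accessible site within 1000 bp of a transcription start site (TSS) in both replicates, against a median of 68.8% for random protein-coding lists matched on gene length (99.96th percentile of 10000 lists). The highest promoter sites of that list were at Cbln3, a secreted synapse organizer of granule cells (height 17.1 ± 6.8, SD, n = 2), at Neurod1, a neuronal basic helix-loop-helix factor (14.2 ± 5.5), and at Zic2, a zinc-finger factor of the granule lineage (13.6 ± 3.9). All 15 pan-neuronal genes (99.17th percentile), with Tubb3 at 11.9 ± 2.7 and the synaptic vesicle gene Syp at 12.8 ± 7.3, all 15 housekeeping genes, with Rplp0 at 31.5 ± 3.4, had a promoter site in both replicates. So did all 16 immediate early genes, with Egr1 at 22.6 ± 8.6 and Jun at 20.4 ± 3.1. The last 2 lists were at the 100th percentile. Over all 21911 protein-coding genes, 14478 (66.1%) had one in both replicates and 6660 (30.4%) in neither.

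Promoters of hepatocyte, erythroid, lymphocyte, microglia, choroid plexus, vascular, Hox, olfactory receptor and Y-linked genes had a site less often than those of matched random lists. None of 13 hepatocyte genes, Alb and Apoa1 among them, had a promoter site in both replicates, nor did any of the 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty (0th and 0.06th percentile). Female animals lack the Y chromosome, so the Y-linked rank checks the labels and says nothing about closed chromatin. Sites were present at 5 of 39 Hox genes, led by Hoxa7 (6.60 ± 4.09), and at 17 of 1134 olfactory receptor genes, with the highest at Olfr1121 (1.89 ± 0.04); both lists were at the 0th percentile. Those counts ask for a site in both replicates: replicate 1 alone had 7 Hox and 37 olfactory receptor genes with a site and replicate 2 alone 10 and 27, still under the 5th percentile. The count was 2 of 12 for microglia, with C1qc at 1.62 ± 0.51 and no promoter site at Aif1, C1qa or C1qb (0.04th percentile). It was 2 of 11 for erythroid genes, with Epor at 2.25 ± 0.70 and Alas2, Gata1 and Hba-a1 closed (0.445th). Choroid plexus and ependyma genes had 1 of 6, where the ciliary regulator Foxj1 reached 5.91 ± 1.73 and Ttr, Folr1 and Clic6 had no site (0.675th, with 2 of 6 in each replicate alone). Lymphocyte genes had 3 of 11, with Lck at 4.43 ± 2.40 and Cd2 and Cd3e closed (0.7th). Vascular and mural genes had 5 of 12, with Flt1 at 0.755 ± 0.380 (0.845th percentile). That rank was lost with replicate 2 alone (9 genes, 49.89th percentile), with replicate 1 alone (7 genes, 10.8th) and with a window of 2500 bp (8.64th).

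Lists of the remaining cerebellar cell types lay inside the range of random lists, between the 5th and 95th percentiles. Purkinje cell genes had a promoter site in both replicates at 11 of 14 members: the calcium release channel gene Itpr1 was the highest (13.6 ± 3.4), followed by Lhx1 (11.9 ± 3.1) and Plcb4 (8.63 ± 1.78), while Pcp2, Ppp1r17 and Skor2 had no promoter site in either replicate. Among interneuron genes the count was 14 of 16, with Ptprk at 2.45 ± 1.07 and the calcium-binding protein gene Pvalb at 2.10 ± 0.71. Unipolar brush cell genes had 7 of 8, led by Calb2 (11.2 ± 6.6). Bergmann glia and astrocyte genes had 10 of 14, with the intermediate filament gene Gfap at 7.85 ± 4.85 and the glutamate transporter gene Slc1a2 at 4.59 ± 0.97. Oligodendrocyte lineage genes had 7 of 13, with the myelin genes Mbp at 3.58 ± 1.45 and Cnp at 2.67 ± 1.27 and no promoter site at Mobp or Sox10. Hindbrain and cerebellar patterning genes had 11 of 14, with En2, a midbrain-hindbrain homeobox gene, at 12.4 ± 4.3 and none at Gbx2 or Lmx1b. Forebrain genes had 11 of 16, with Lhx2 at 1.78 ± 0.77, Tbr1 at 1.55 ± 0.03 and no site at Fezf2. Imprinted genes had 14 of 16, with Snrpn at 11.4 ± 4.4 and no site at Igf2. All 5 genes that escape X inactivation or silence X had a site, from 1.75 ± 0.68 at Xist to 29.8 ± 7.4 at Kdm6a. The other counts were 37 of 56 clustered protocadherins and 5 of 12 striated muscle genes, with Mylpf at 9.47 ± 6.30, Ckm at 7.61 ± 5.48 and Acta1 at 0.932 ± 0.043. In the shorter list, the protocadherins (0th percentile) and the muscle genes (0.465th) fell under the 5th percentile and the imprinted genes (95.92nd) passed the 95th. Random lists not matched on length put the muscle genes at the 4.825th and the interneuron and imprinted genes at the 96.89th, and a window of 2500 bp put the imprinted genes at the 97.31st. With replicate 2 alone the interneuron (99.28th), forebrain (98.36th) and imprinted (97.45th) genes passed it. With replicate 1 alone the Bergmann glia and astrocyte (96.69th) and hindbrain (97.4th) genes did.

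**Figure D1:**
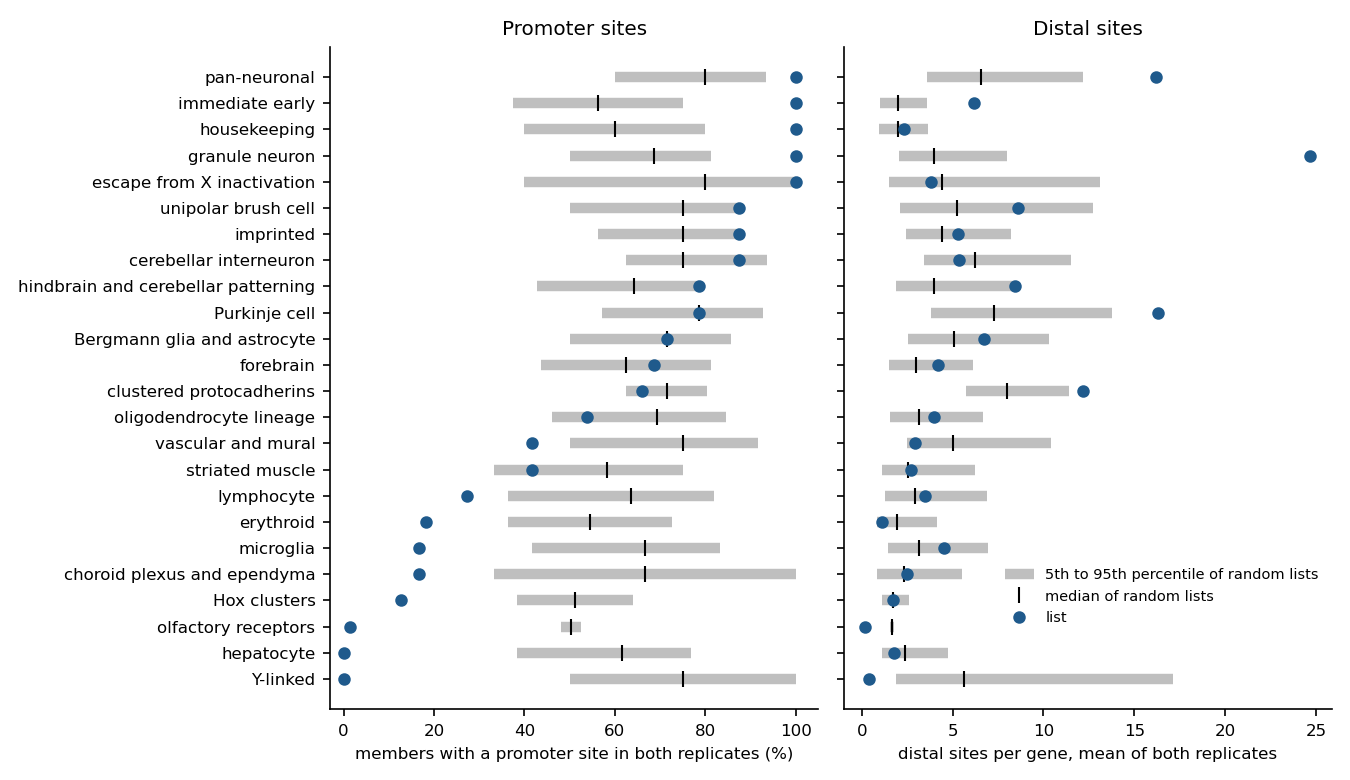
Accessible sites of 24 gene lists; left, the percentage of members with a promoter site in both replicates, right, distal sites per gene averaged over both replicates, with grey bars for the 5th to 95th percentile and ticks for the median of 10000 random lists matched on gene length. Granule neuron genes lie at 100% on the left and at 24.7 distal sites per gene on the right, and olfactory receptors, with 17 of 1134 members, at 0.157 on the right.

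Granule neuron, Purkinje cell and pan-neuronal genes had more sites away from promoters than matched random lists, while interneuron, unipolar brush cell and forebrain genes did not stand apart. Granule neuron genes had 24.7 ± 5.7 (SD, n = 2) distal sites per gene in the gene body and 10 kb on each side, against a median of 3.97 in matched random lists (99.93rd percentile). The splicing regulator gene Rbfox3, which encodes the neuronal nuclear antigen NeuN, alone had 142.5 ± 14.8; the other 15 members averaged 16.8 ± 5.1 (99.9th percentile), so the call did not rest on it. Immediate early genes had 6.16 ± 1.72 (99.99th percentile, but the 86.95th among lists not matched on length), pan-neuronal genes 16.2 ± 6.1 (98.94th) and Purkinje cell genes 16.3 ± 4.3 (97.95th), among them Plcb4 with 65.0 ± 25.5. Clustered protocadherins had 12.2 ± 1.2 (96.86th, and the 93.41st with replicate 2 alone); their gene models share exons, so 1 site can count for several of them. Hindbrain and cerebellar patterning genes had 8.43 ± 1.92 (95.06th, but the 67.38th in the gene body alone and the 94.45th with replicate 2 alone), with Meis1 at 31.5 ± 4.9. The lists with few were olfactory receptors at 0.157 ± 0.014 (0th percentile) and Y-linked genes at 0.375 ± 0.530 (0.055th), whose chromosome female animals lack. The other 16 lists lay between the 5th and 95th percentiles, at 6.75 per gene for Bergmann glia and astrocytes, 3.96 for the oligodendrocyte lineage, 4.50 for microglia, 5.38 for interneurons (34.82nd percentile), 8.63 for unipolar brush cells (81.91st), 4.19 for forebrain genes (78.26th) and 1.77 for hepatocytes.

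The 10 protein-coding genes with the most shared distal sites had annotated models of 352.9 to 4435 kb, and the count was not scaled by length. Rbfox3 had 106 shared sites over 421.8 kb, Rbfox1, another splicing regulator, 105 over 1526 kb, the cell adhesion gene Ntm 94, Camta1 85, Nav2 79, the adhesion gene Lsamp 72 over 2197 kb and Gse1 70. The others were Gm20388 (362 sites over 4435 kb), Fgfr2 (167 over 2961 kb) and Gm37240 (69 over 1391 kb). The count takes in every distal site of the annotated span, also where other genes lie within it. The model of Gse1 lies within that of Gm20388, so its 70 sites count for both. The replicates differed most at Ntm, with 111 distal sites in replicate 1 and 280 in replicate 2, and at Rbfox1, with 118 and 260.

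Most of the highest sites of the genome were at promoters, and 3 of the 10 highest held a CTCF consensus match. Of the 10 shared sites with the best mean rank of height, 8 were within 1000 bp of a TSS. They included the promoters of Dynlt1b, a dynein light chain gene (chromosome 17, 6430001 to 6430180, height 55.9 ± 9.7), Acin1 (chromosome 14, 54686561 to 54686880, 45.6 ± 13.9), the nuclear pore gene Nup107 (chromosome 10, 117792761 to 117792940, 48.9 ± 27.6), Rragc (chromosome 4, 123917261 to 123917480, 42.5 ± 19.3) and Ipmk (chromosome 10, 71347561 to 71347760, 43.2 ± 21.6). A site near 2610005L07Rik (chromosome 8, 20424721 to 20424940, 51.8 ± 17.6), one near Gm21769 (chromosome 8, 20122141 to 20122300, 46.8 ± 18.1) and an intronic site whose nearest TSS is that of Cd5 (chromosome 19, 10709501 to 10709660, 47.0 ± 23.1) each held a CTCF consensus match. An intergenic site lay 4945 bp from the TSS of Txn2 (chromosome 15, 77933841 to 77934060, 41.9 ± 16.2). The site near Gm42418 (chromosome 17, 39846781 to 39846900) was at 47.1 in replicate 1 and 73.3 in replicate 2, and it was the only one of the 10 whose middle 50 bp occurred more than once in the assembly (2 exact copies). On the authors' scale the other 9 were higher in replicate 1; in unscaled steps 6 of the 10 were, and the sites at Dynlt1b, Acin1 and 2610005L07Rik were also higher in replicate 2.

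Most strong sites were present in both animals. Replicate 1 had 132033 sites and replicate 2 had 159142 (mean 145588 ± 19169), with median widths of 180 and 211 bp, covering 0.910% and 1.44% of the genome. Of the sites in replicate 1, 76.3% overlapped a site of replicate 2 by at least 1 bp, and 61.1% of the sites in replicate 2 overlapped one of replicate 1; the same sites placed at random on their chromosomes gave 2.65% and 2.20%. The share rose with height, from 28.1% to 99.1% between the lowest and the highest decile of replicate 1 and from 9.44% to 99.5% in replicate 2 (Wilson 95% intervals within 1 percentage point). Across the 94816 paired sites the heights had a Pearson correlation of 0.944 on the log2(height + 1) scale and a Spearman correlation of 0.928; sites are not independent replicates, so no p-value is attached.

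**Figure D2:**
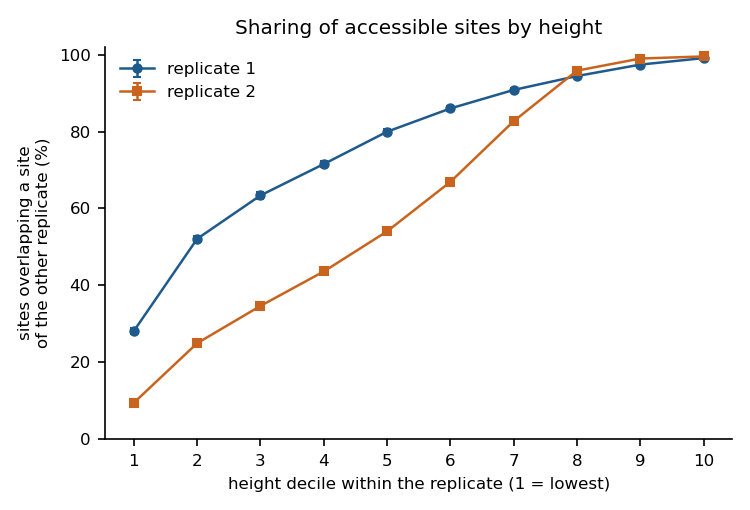
Percentage of accessible sites that overlap a site of the other replicate, by height decile within each replicate; bars are Wilson 95% intervals. Sharing rises from 28.1% to 99.1% in replicate 1 and from 9.44% to 99.5% in replicate 2.

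Sites found in 1 replicate alone were low. The 31302 sites of replicate 1 alone had a median height of 0.376 against 1.22 for its shared sites, and the 61963 of replicate 2 alone had 0.268 against 0.950. The 3 highest of each lay near promoters, those of Gm29477 (height 17.6), Tmpo (16.7) and Phyhipl (16.5) in replicate 1 and those of Junos (13.6), Mon1b (12.4) and Rmnd5a (10.8) in replicate 2, and each was 0 to 140 bp from a site of the other replicate. Of all such sites, 17.5% in replicate 1 and 6.97% in replicate 2 were within 150 bp of a site of the other animal, and of the 1000 highest 67.1% and 41.5% were.

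On the authors' scale, shared sites were higher in replicate 1, and most of all where a CTCF consensus was present. The median log2 ratio of replicate 1 over replicate 2 was 0.43 (SD across sites 0.61), and 78.5% of shared sites were higher in replicate 1. This direction rests on the authors' scaling: in unscaled steps the median log2 ratio was -0.28 and 31.8% of shared sites were higher in replicate 1. The log2 difference between sites with and without a consensus is the same on either scale. CTCF, the zinc-finger protein of chromatin loop anchors and insulators, had a consensus match within the middle 150 bp of 11610 shared sites. Their median log2 ratio was 1.18 (SD 0.61), a 2.27-fold difference, against 0.36 (SD 0.55) at the 83206 others, and 95.8% of them were higher in replicate 1. In unscaled steps the medians were 0.48 (1.39-fold, 75.8% higher in replicate 1) with the consensus and -0.35 (25.6% higher in replicate 1) without it. The CTCF sites were singled out after their values were seen. Among the 27 consensus sequences compared, CTCF had the largest difference at matched height (0.79). The palindromic NFI consensus came next (0.35), with a median of 0.77 at 106 sites against 0.43 without it. Sites with NRF1 (0.72) and SP/KLF (0.69) matches also had higher medians, but at matched height their differences were 0.06 and 0.10. Sites with matches of MEF2 (0.23), ROR (0.20) and NEUROD/ATOH1 (0.35) had lower medians than sites without them (0.43, 0.43 and 0.44), by less than the spread between sites. With 1 library per animal, these differences compare 2 libraries and have no test against the variation between animals.

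**Figure D3:**
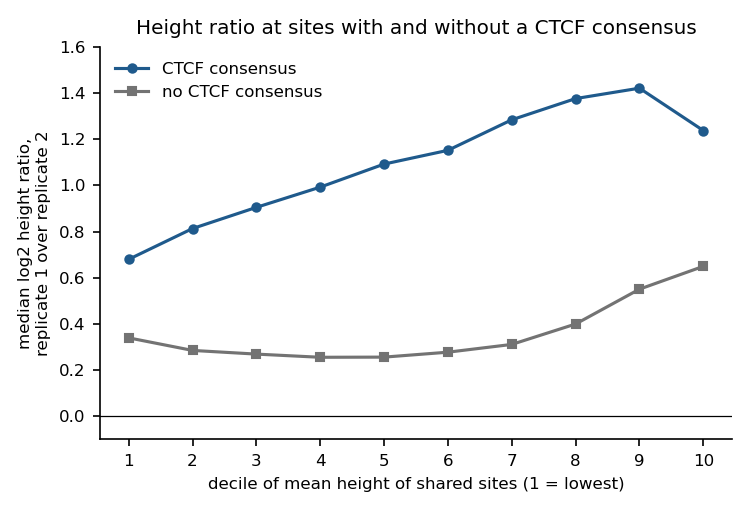
Median log2 ratio of site height, replicate 1 over replicate 2, by decile of mean height on the authors' scale, for shared sites with and without a CTCF consensus match. The CTCF sites lie at 0.68 in the lowest decile and 1.42 in the ninth, the others at 0.34 and 0.55.

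Promoters held 29.7% ± 2.7 of the sites (SD, n = 2), 4.31 ± 0.47 times the share of randomly placed sites. Introns held 38.3% ± 2.7, intergenic sequence 25.5% ± 0.5 and exons 6.45% ± 0.50. The X chromosome had 21.9 ± 1.0 sites per Mb against 57.6 ± 7.7 on the autosomes, a ratio of 0.382 ± 0.034. Chromosome 11 was the densest, at 87.8 ± 12.5 sites per Mb, and chromosome 3 the least dense autosome, at 41.6 ± 5.0. The Y chromosome, which female animals lack, had 40 sites in replicate 1 and 63 in replicate 2, a density of 0.00963 ± 0.00179 of that on the autosomes.

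Footprints numbered 291220 in replicate 1 and 529003 in replicate 2, with median widths of 11 and 10 bp, and 88.3% and 78.3% of them lay in accessible sites. Footprints of replicate 1 overlapped one of replicate 2 in 61.9% of cases, and the reverse share was 34.6%. For footprints inside sites the shares were 61.4% and 39.2%, against 43.3% and 27.4% when each footprint was moved at random within its own site. Inside the paired sites, replicate 1 had 2.65 footprints per site and replicate 2 had 3.76. The promoter site of Neurod1 (chromosome 2, 79456561 to 79457020, height 18.1 and 10.3) held 10 footprints in each replicate. A footprint of replicate 1 that overlaps one of replicate 2, upstream of the annotated gene at 79456971 to 79456982, covers AAAGTGGCCCAT, and with 5 bp on each side (AGAAGAAAGTGGCCCATCTGTC) it holds an E-box of the NEUROD/ATOH1 type. In the promoter site of Cbln3 (chromosome 14, 55884201 to 55884420), a footprint of replicate 1 that also overlaps one of replicate 2, at 55884297 to 55884324 within the annotated gene span, covers TGAGTCTGGCACCTAGCCCGGGCACTCC and holds the short NFI site.

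Footprints were rich in matches of CTCF and of several promoter and neuronal factors. Set against windows of the same width elsewhere in the same site, 13 of 27 consensus sequences were more frequent in footprints and 9 less frequent in both replicates (95% interval of counting error leaving out 0). CTCF had a mean log2 ratio of 4.42 ± 0.24 (SD, n = 2), a 21.4-fold excess. Its matches were in 2.41% and 1.51% of the footprints that had a background window in their own site (4753 and 5601 footprints). Among footprints with a window 1 kb away, the shares were 4.91% and 2.99% (11479 and 10259 footprints). The pairing within sites thus left out many footprints with a CTCF match. The size of the excess depended on the setting: for CTCF it was 83.5-fold without extending the footprints, 32.7-fold against windows 1 kb away and 32.2-fold over 1000 bp from a TSS. For NRF1 it went from 11.4-fold to 30.3-fold and 64.0-fold with the first 2 of these. NRF1 had 3.51 ± 0.24, CRE, the element bound by CREB, 3.33 ± 0.03 and SP/KLF 3.02 ± 0.17. The palindromic NFI site had the highest mean, 6.90 ± 1.24, but its value rests on the 0.5 added to each count, since it was found in 97 and 109 footprints and in 1 and 0 background windows; the short NFI site, found in 8.96% and 7.13% of footprints, had 1.23 ± 0.12. The E-box of NEUROD/ATOH1, factors of the granule lineage, had 1.54 ± 0.03, a 2.90-fold excess (4.63-fold against windows 1 kb away), and ZIC had 2.16 ± 0.39. The lowest ratios were those of PU.1 (-1.05 ± 0.01), ROR (-1.03 ± 0.02), GATA (-1.01 ± 0.05), MEF2 (-0.94 ± 0.23) and the LHX/POU octamer (-0.91 ± 0.16).

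Base composition bears on these counts, since footprints were richer in G and C than the windows they were set against (60.4% against 55.2% in replicate 1, 59.1% against 54.7% in replicate 2). Against their own consensus with the letters permuted, a control added after the data were seen, 8 of the 13 stayed above every permuted version in both replicates: CTCF, NRF1, ETS, CRE, both NFI forms, the E-box of NEUROD/ATOH1 and ZIC. SP/KLF, RFX, EGR, YY1 and the E-box of MYOD/ASCL did not, and none of the 9 less frequent ones lay below all of their permuted versions. The excess of ETS (0.74 ± 0.01) was not found in sites over 1000 bp from a TSS, where its log2 ratio was -0.15.

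**Figure D4:**
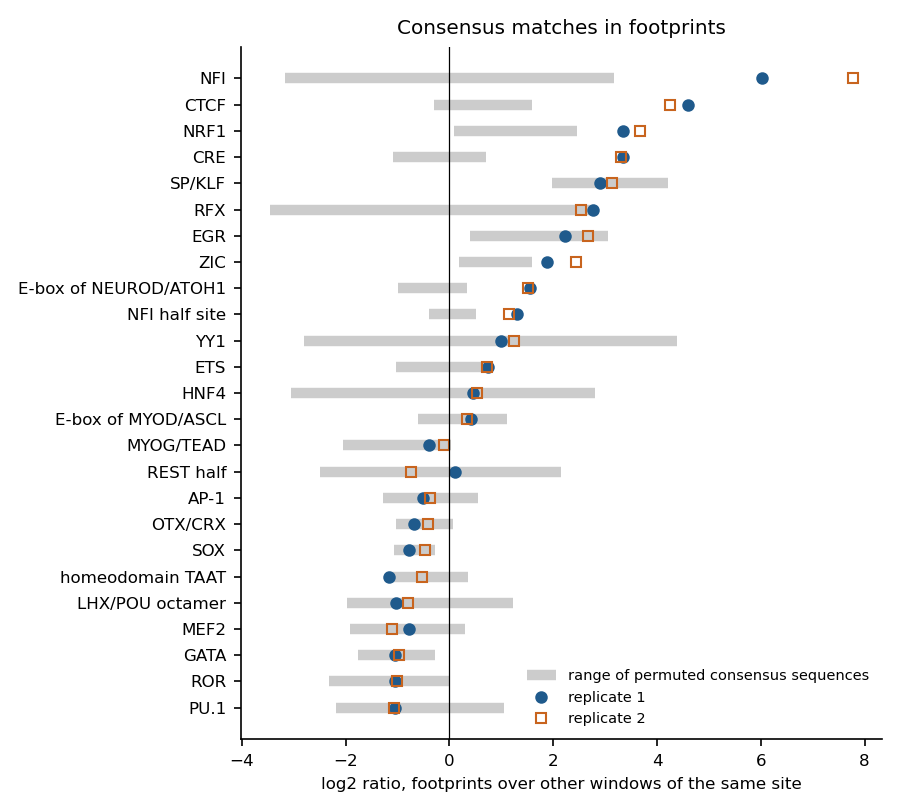
Log2 ratio of consensus matches in footprints over other windows of the same site, per replicate, for 25 consensus sequences (HNF1 and P53, with no match, are left out); grey bars span the values of up to 10 permuted versions of each consensus over both replicates. CTCF lies at 4.59 and 4.25, beyond its bar, and SP/KLF at 2.90 and 3.14, within it.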

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

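Alternatives against permuted consensus sequences, without Rbfox3, without CTCF sites, with heights in unscaled steps, with footprints in stretches of FDR 0.001 or less, and with the shorter list of one animal set against the longer list of the other were chosen after seeing the data; the rest were planned. The cause of the changes below was not tested except where the setting itself gives it (fewer sites, wider windows). No paired analysis was possible because there is 1 group. A stricter footprint threshold was not run, since the footprint files hold 1 constant value.

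The shorter list (all sites touching bases with FDR of 0.001 or less) lowered the mean number of sites to 93914 and the X to autosome ratio to 0.346. It raised the promoter share to 35.7%, and promoter windows of 500 and 2500 bp gave 22.8% and 40.3%. Reciprocal overlap of 50% lowered the mean share of shared sites from 68.7% to 51.7%, and the shorter list against the longer one raised it to 82.9%. The correlations of heights (Pearson, Spearman) were 0.939 and 0.928 with a pseudocount of 0.01, 0.943 and 0.931 with reciprocal overlap, 0.958 and 0.936 without CTCF sites, and 0.851 and 0.554 over the union with missing sites at 0. With 1 replicate left out in turn, 6 to 7 lists stood at or above the 95th percentile for promoters in place of 4. Random lists not matched on length gave 4 in place of 2 lists with few distal sites. In unscaled steps the median log2 height ratio of replicate 1 over replicate 2 turned from 0.43 to -0.28 over all shared sites and from 0.36 to -0.35 over those without a CTCF consensus; it kept its sign with one (1.18 to 0.48). Of the 13 motifs more frequent in footprints 8 lay above all of their permuted versions, and of the 9 less frequent ones 0 lay below all of theirs.

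Among motifs called more or less frequent, 7 alternative values had the other sign, differences from permuted sequences included. Another 93 of the 189 alternative values of all motifs did not stay within the spread between replicates. That count takes in unchanged values of HNF1 and P53, which had no match and a spread of 0. For the other motifs, leaving out 1 replicate stays within the spread by construction, so those values say nothing about stability. The value against permuted sequences is another measure, the log2 ratio minus the mean log2 ratio of the permuted versions. It was 0.069 for AP-1, 0.28 for MEF2, 0.064 for SOX and 0.14 for ROR, whose own log2 ratios were below 0. With windows 1 kb away the log2 ratio itself was 0.13 for AP-1 and 0.10 for ROR, and over 1000 bp from a TSS it was -0.15 for ETS. HNF4, the REST site and MYOG/TEAD, which were called neither, also crossed 0. Of the 144 alternative percentiles of promoter lists 129 kept their side of both limits, and of the 145 for distal sites 137 did; 3 and 4 fell back between the limits, and 12 and 4 passed one. With 2 libraries, differences between animals cannot be separated from those between libraries, and if a height step stands for 1 count, the lower depth of replicate 1 limits what can be said of its low sites.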

Other observations

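The tests of list promoters and of heights in unscaled steps, of motifs in single-replicate sites, of CTCF sites within height and GC deciles, of footprints inside the same intervals, and of few steps and a male animal for Y were chosen only after the result was seen. The ratio of promoter heights between the animals stood apart from that of other promoters of like height in 7 of 18 gene lists: higher in 2 and lower in 5. Clustered protocadherins, cell adhesion genes whose promoters are chosen one by one in each neuron, were 1.87-fold higher in replicate 1 on the authors' scale (median log2 ratio 0.90, SD 0.70, 33 of 37 promoters) and 1.14-fold in unscaled steps (0.19, 25 of 37). The scale does not move their place among random lists, which was above all 10000 random lists matched on promoter height (median 0.45). These genes are neighbours on chromosome 18, while the random lists draw genes from the whole genome. Their promoters are therefore not independent members, and 1 difference at that locus could give this place. Bergmann glia and astrocyte promoters were at 0.05 (SD 0.57, 0.36th percentile) and hindbrain and cerebellar patterning promoters at 0.23 (2.725th). The 5 striated muscle promoters, 3 of them higher in replicate 1 on the authors' scale, were at 0.09 (SD 1.28, 2.805th). Interneuron promoters were at 0.22 (4.57th) and olfactory receptor promoters at 0.11 (0.585th). In unscaled steps these 5 lists turned to -0.66, -0.48, -0.62, -0.49 and -0.60, in the same order, so only their place among random lists, not which animal was higher, is independent of the scale. Hox promoters were at 0.92 (95.81st, 5 promoters; 0.21 in unscaled steps). Random lists were first matched on gene length; the match on height was chosen after those values were seen, because ratios vary with height. Of 18 lists, 2 lay at or above the 95th percentile and 5 at or under the 5th with the height match, and 1 and 5 with the length match, under which Hox was at the 94.59th and Bergmann glia and astrocytes at the 0th. Oligodendrocyte promoters, at 0.85 (94.9th), and granule neuron promoters, at 0.60 (44.69th), lay between the 5th and 95th percentiles, as did the other 9 lists with at least 5 promoters open in both. Within the glial list, Gfap was at 11.3 in replicate 1 and 4.42 in replicate 2. At Mbp, replicate 1 had 25 distal sites and replicate 2 had 14, against the usual direction of more sites in replicate 2. The CTCF consensus used here was present in the highest promoter site of 1 of 36 protocadherins, and the others had a median log2 ratio of 1.01. Only the middle 150 bp of that site was searched for this 1 sequence, so a part of CTCF in their difference cannot be judged.

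Single-replicate sites also differed in sequence from shared ones, in a comparison not matched on height. The CTCF consensus was present in 12.2% of shared sites, in 7.33% of sites in replicate 1 alone (Wilson 95% interval 7.05 to 7.62) and in 1.77% of those in replicate 2 alone (1.67 to 1.88). The E-box of NEUROD/ATOH1 was present in 10.2%, 5.96% and 5.66%, and the GATA consensus in 0.533%, 0.808% and 0.851%. Single-replicate sites were low, and the CTCF share varied with height. Among shared sites it was 6.97% in the lowest decile of mean height and 20.8% in the ninth. The lower CTCF share in replicate 2 alone is not independent of the greater height of CTCF sites in replicate 1.

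The excess of replicate 1 at CTCF sites, found by comparing 27 consensus sequences and tested on the same data, is a hypothesis about CTCF. If replicate 1 had raised strong sites more than weak ones, the excess over other sites would have closed within deciles of mean height, but the log2 difference stayed at 0.79 (SD over deciles 0.21). GC content is argued against in the same way, with a difference of 0.86 (SD 0.18) within GC deciles. Sites with a footprint over the consensus in both replicates exceeded those with a footprint in neither by 0.80 after matching on height, which is consistent with a difference tied to occupied CTCF sites. A candidate explanation that stays open is the extent of digestion or the size of the fragments sequenced, on which no value was measured here; whether CTCF occupancy itself differed between the animals was not tested.

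The greater number of footprints in replicate 2 could come from greater depth, if a height step stands for 1 count. Wider sites cannot be judged. Inside intervals that join both sites of a pair, replicate 2 had 1.42 times as many footprints per site. These intervals keep flanks that lie in the site of 1 replicate alone, and replicate 2 had the wider sites (median 211 against 180 bp over all sites). At equal height in steps, a stand-in for equal counts, the ratio was 1.33 (SD over height classes 0.15), from 1.59 in the lowest class to 1.14 in the highest, with 1.44 in 2 classes between; the change from 1.42 is smaller than that spread. Depth and other differences between the libraries cannot be told apart here, because the height of a site is not its total number of cuts. No biological explanation was tested.

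Sites on the Y chromosome of female animals may reflect sequence shared with X or an autosome: 82.4% of Y sites (mean of the replicates, SD 6.9) had at least 25% of their 24-base words elsewhere in the assembly, against 13.8% and 14.2% of X sites. A stretch of Y before Mid1-ps1, with sites from 90717601 to 90744820, held 25 of the 40 sites of replicate 1 and 20 of the 63 of replicate 2, among them one at 90744601 to 90744820 with a height of 20.9 in replicate 1, whose words matched X near 169987026, inside Mid1; 16 and 14 sites of the stretch passed the 25% limit. A male animal is argued against by the promoters of Ddx3y, Eif2s3y and Uty, which had no site in either replicate. Kdm5d had one in replicate 1 alone, at a height of 0.0185. The Y density of 0.00963 of the autosomal one cannot decide this, since the density in a male animal was not measured here. Sites of very few counts over an empty background are a further open explanation for part of the sites. Of the Y sites, 17.9% (SD 21.8) had 4 steps or less, 1 site in replicate 1 and 21 in replicate 2. Some sites of the stretch, found in both replicates, are covered by neither explanation. Those starting at 90738981 had 141 and 172 steps, and those at 90739621 and 90739561 had 153 and 195. All of these had 0% of their words elsewhere.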
